A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

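The series holds 6 libraries of polyadenylated RNA from 3 strains of Saccharomyces cerevisiae, 2 aerobic bioreactor cultures each: IMX605 (libraries R12 and R7), IMX606 (R13 and R8) and IMX372 (DSE001 and DSE002). Per the labels' protocols, RNA was extracted with hot phenol, and libraries were made with a TruSeq stranded mRNA kit and sequenced on an Illumina HiSeq instrument. The labels state that the IMX372 libraries come from an earlier deposit, so the comparisons against IMX372 are also comparisons between library sets. The submitters' processing notes name STAR 2.5.4a, SAMtools, featureCounts, edgeR and DESeq2 without giving the role or order of each. The strand setting of the counting and the name of the genome build are not given in the sources used here.

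The values used are the FPKM values as deposited by the authors, 1 table of 5625 genes by 6 libraries with gene coordinates on CEN.PK113-7D sequences. Each value times the gene length sums to the same total per library, and 100% of values are whole multiples of a single step per library (tolerance 0.01). Reads on genes were therefore recovered as whole numbers, 18754741 to 21370278 in 5 libraries and 70510681 in IMX372 DSE001. A floor of 3 reads at 1 kb lies between 0.0425 and 0.160 FPKM, and the 10 most abundant genes take 7.98% to 10.7% of the reads on genes. Of the gene names, 5550 match the reference table, which was used for names, neighbour order and near-identical copies only. Gene models that share a name (287) carry a model number and are in no list.

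Log2(FPKM + 1) values of genes with a mean of at least 1 FPKM (5459 genes, 166 below) were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per strain and an intensity trend. The residual degrees of freedom were 3, the prior degrees of freedom 8.38 and the median residual SD 0.116. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in IMX605 against IMX372, IMX606 against IMX372 and IMX605 against IMX606. Tested on simulated data with 200 changed genes among 5459, the fit recovered 89.0% of 1.5-fold and 98.5% of 2-fold changes for IMX605 against IMX372, 82.6% and 97.5% for IMX606 against IMX372, and 85.6% and 98.0% for IMX605 against IMX606, with 5.27%, 5.56% and 5.03% false calls. Gene lists (28, of which 26 held genes above the filter) were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. The 4 mitochondrial genes with a model in the list for RNA quality were all under the filter, and the list of small nuclear and nucleolar RNAs had 0 gene models. The sum over the 13 relocated genes was compared by exact permutation of the cultures. Shared controls were examined with 100 simulations of unchanged groups.

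The comparisons, tests, lists and the rule for naming genes were set before the data were examined. The rule names the 10 largest rises and falls of each comparison, up to 4 called members of each list with the smallest adjusted p, every relocated gene, minor paralog and label check gene, and up to 10 called genes with the largest changes among the neighbours of native loci, the nearest gene on each side. Near-identical copies are genes with at least 95% identity over 200 bases (BLAST 2.17.0), and opposite-strand neighbours are genes within 500 bases at 10 times the level or more. A gene whose span overlaps another gene by that length also counts as having a copy. Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median-of-ratios factors (0.970 to 1.05), equal sums, quantile normalization, fits of only the 2 groups compared, limma without the trend, each library left out, camera with an estimated correlation, and fry. Added after seeing the data were voom on the recovered reads, 1 control library for each comparison, and tests without genes that have copies or opposite-strand neighbours. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and figures. The planned tests on deposited counts were not run because the table holds FPKM, and the raw reads were not used here.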

Results

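Polyadenylated RNA was measured by RNA sequencing in 3 strains of the yeast Saccharomyces cerevisiae that differ in where their genes of glycolysis and alcoholic fermentation sit. Per the labels, these genes were placed together at a single locus, on chromosome V in IMX605 and on chromosome IX in IMX606. In IMX372 the major paralogs were left at their native loci. Each strain was sampled from 2 aerobic bioreactor cultures, described in the labels as biological duplicates. The libraries held 20124583 and 19490736 reads on genes for IMX605 (libraries R12 and R7), 18754741 and 21370278 for IMX606 (R13 and R8), and 70510681 and 19100242 for IMX372 (DSE001 and DSE002). A floor of 3 reads on a gene of 1 kb stood at 0.0425 to 0.160 FPKM, which covers counting error only. The IMX372 libraries were reused from an earlier deposit, so library set and strain cannot be told apart in both comparisons against IMX372. The 13 genes followed here as relocated are the major glycolytic and fermentative paralogs of a list drawn up from general knowledge, because the labels do not enumerate them. Coordinates are those of the deposited table, on CEN.PK113-7D sequences whose build is not given in the sources used here. Fold changes are on the log2(FPKM + 1) scale, which understates the changes of low genes, and tests are limma's with Benjamini-Hochberg adjustment.

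The first question was whether the relocated genes were transcribed alike from one locus and from their native loci. PGK1, which encodes phosphoglycerate kinase (chromosome III, 142895 to 144145), showed the largest difference of the 13, with 2107 ± 109.6 FPKM in IMX605 and 2416 ± 385 in IMX606 against 6225 ± 893 in IMX372 (SD, n = 2 each). That was 33.8% and 38.8% of the IMX372 mean, with log2 changes of -1.56 (SE 0.13, adjusted p = 5.41e-06) and -1.37 (SE 0.13, adjusted p = 1.78e-05) by limma. ENO2, an enolase, rose from 6579 ± 1011 FPKM in IMX372 to 9898 ± 51.5 in IMX605 and 9396 ± 452 in IMX606, by 0.60 and 0.52 on the log2 scale. GPM1, phosphoglycerate mutase, rose by 0.53 and 0.47, and the phosphofructokinase genes PFK1 and PFK2 rose by 0.43 and 0.44 in IMX605 and by 0.61 and 0.57 in IMX606. TDH3, glyceraldehyde-3-phosphate dehydrogenase, read 19697 ± 1053 and 18956 ± 453 FPKM against 12472 ± 2273, a rise of 0.67 and 0.62 that is uncertain because the gene shares near-identical sequence with TDH2.

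ADH1, the main alcohol dehydrogenase, fell to 7334 ± 839 and 7179 ± 477 FPKM from 10034 ± 1797 in IMX372, with log2 changes of -0.45 (adjusted p = 0.0222) and -0.47 (adjusted p = 0.0209) by limma. The pyruvate kinase gene CDC19 and the pyruvate decarboxylase gene PDC1 rose in IMX605, by 0.30 (adjusted p = 0.0394) and 0.66 (adjusted p = 0.0357). In IMX606 their changes of 0.20 (adjusted p = 0.165) and 0.45 (adjusted p = 0.142) did not pass. The PDC1 change in IMX606 ranged from 0.03 to 0.88 over the settings tried, and the IMX606 cultures read 7136 (R13) and 3957 (R8) FPKM. HXK2, PGI1, FBA1 and TPI1 passed in neither strain, with levels between 88.0% and 113.9% of the IMX372 mean. In IMX605 7 of the 13 genes rose, 2 fell and 4 did not pass, and in IMX606 5 rose, 2 fell and 6 did not pass. Adjusted over the list alone the counts were the same, 7 and 2 in IMX605 and 5 and 2 in IMX606. As a list the 13 genes showed no shift in a single direction relative to other genes (camera, adjusted p = 0.179 and 0.198). Rises and falls can cancel in that test. Fry for changes in either direction passed the list (adjusted p = 0.000199 and 0.000253), as it did 26 and 24 of the 26 lists. Between IMX605 and IMX606, limma and voom each called 0 of the 13, and 1 (HXK2) had an unadjusted p under 0.05. PDC1 was called in that comparison when IMX606 R13 was left out (0.63, adjusted p = 0.0261).

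The calls of PGK1 and TDH3 in both strains, and of ENO2 in IMX605, held in every setting tried for them. Each of the other calls of the 13 genes ended with some library left out. Such a fit has fewer libraries, so an ended call does not by itself show that the change rested on the library left out. In IMX605 the PFK1 change of 0.43 grew to 0.53 without IMX372 DSE001 and shrank to 0.34 without IMX372 DSE002, and the call ended both times. Leaving out IMX372 DSE002 ended those of PFK1 (adjusted p = 0.192), PFK2 (0.125), GPM1 (0.0694), CDC19 (0.238) and PDC1 (0.278) in IMX605, and of PFK1 (0.0881), PFK2 (0.0653), GPM1 (0.114) and ENO2 (0.0728) in IMX606. Without IMX372 DSE001 the calls of PFK1 (0.0537), PDC1 (0.0890) and ADH1 (0.188) in IMX605 and of ADH1 in IMX606 (0.170) ended. Leaving out IMX605 R12 ended those of PFK1 (0.0718), PFK2 (0.0615), CDC19 (0.0692), PDC1 (0.111) and ADH1 (0.135), and leaving out IMX605 R7 those of PFK1 (0.113), PFK2 (0.0719) and CDC19 (0.212). Without IMX606 R8 the GPM1 call in IMX606 ended (0.0703) while PDC1 passed there (0.88, adjusted p = 0.000113), and without IMX606 R13 the ADH1 call ended (0.0696). The ADH1 calls also ended with median-of-ratios scaling (adjusted p = 0.0736 and 0.0819) and without the filter on low values (0.0929 and 0.0930), as did those of CDC19 and PDC1 in IMX605 (0.0624 and 0.0645 with that scaling, 0.0780 and 0.141 without the filter). Without the filter those of PFK1 in IMX605 (0.0707) and GPM1 in IMX606 (0.0617) ended too, without limma's trend those of CDC19 (0.0800), PDC1 (0.0674) and ADH1 (0.0511) in IMX605, and with equal sums (0.0617) or quantile normalization (0.0576) that of CDC19. Quantile normalization instead added falls of FBA1 in both strains (adjusted p = 0.000153 and 0.000164).

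**Figure D1:**
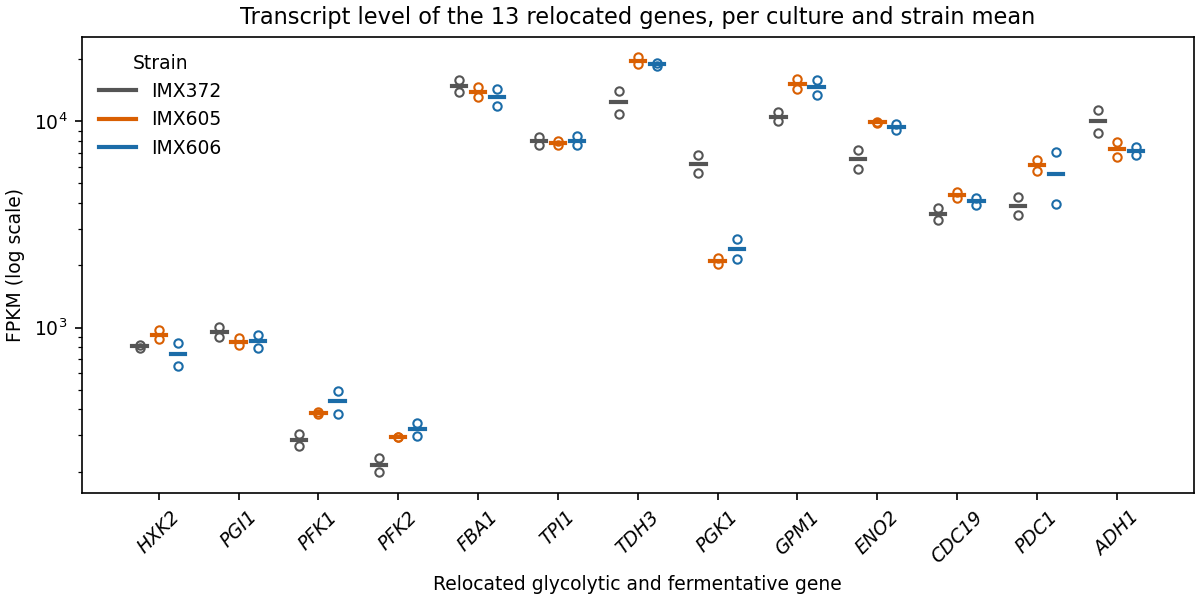
FPKM (log axis) of the 13 relocated genes in each culture (open circles) with the mean of each strain (bars) for IMX372, IMX605 and IMX606. PGK1 lies at 2107 and 2416 FPKM in the single-locus strains against 6225 in IMX372, while TPI1 lies at 7898, 8079 and 8039 FPKM.

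Summed over the 13 genes, transcript amounted to 89054 ± 4561 FPKM in IMX605, 85850 ± 2788 in IMX606 and 78557 ± 9703 in IMX372 (SD, n = 2 each). These sums took 9.70%, 9.32% and 8.56% of the reads on genes. IMX605 exceeded IMX372 by 10497 FPKM and IMX606 exceeded it by 7293 FPKM. The 2 IMX605 cultures lay above both IMX372 cultures, but IMX605 R12 and IMX372 DSE001 lay close (85829 and 85418 FPKM). The IMX606 cultures overlapped those of IMX372. The order of single cultures was not compared under other scalings. Two-sided exact permutation tests gave p = 0.333 for IMX605 against IMX372, 0.667 for IMX606 against IMX372 and 0.667 between the single-locus strains, where 0.333 is the smallest p that groups of this size allow.

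Of the minor glycolytic paralogs, isoenzyme genes outside the relocated set, 6 of the 12 with a gene model passed the filter on low values, and all 6 lay far below their major paralogs. The highest strain mean among the 12 was 33.3 FPKM, that of TDH2 in IMX372. Whether the strains still carry these genes was not tested, so the changes below are changes in the few reads assigned to them. HXK1, a hexokinase, rose from 0.325 FPKM in IMX372 to 4.57 in IMX605 and 4.66 in IMX606, by 2.07 (adjusted p = 0.000117) and 2.04 (adjusted p = 0.000144) by limma. HXK1 lies beside a far more abundant gene on the opposite strand, so its reads are uncertain. TDH2 read 4.80 ± 4.47 and 6.65 ± 0.331 FPKM against 33.3 ± 14.4 in IMX372, a fall of 2.75 and 2.10 on the log2 scale that is uncertain because of its copy TDH3 and that ended in IMX606 without IMX372 DSE002 (adjusted p = 0.120) and without the filter (0.0617). ADH4 fell by 0.95 and 0.76, calls that ended without IMX372 DSE002 (adjusted p = 0.0909 and 0.193) and, in IMX606, without IMX606 R13 (0.0554) or IMX372 DSE001 (0.0505). ADH2 rose in IMX605 by 1.39 (adjusted p = 0.0159), a call that ended without IMX605 R12 (0.113), without IMX372 DSE002 (0.190) and without the filter (0.0754). Its change in IMX606 was 1.08 (adjusted p = 0.0558), which passed without IMX605 R12 (0.0291), IMX605 R7 (0.0262) or IMX606 R8 (0.000758), with a pseudocount of 0.1 (0.0432) and with only the 2 groups in the fit (0.0292). TDH1 and ENO1 did not pass, and TDH1 was called in IMX605 without IMX606 R13 (0.0244) or R8 (0.0228) and with only the 2 groups in the fit (0.0229). In IMX605 2 rose and 2 fell, and adjusted over the list alone 2 rose and 3 fell. In IMX606 1 rose and 2 fell, and adjusted over the list alone 2 rose and 2 fell. The list showed no shift in a single direction (camera, adjusted p = 0.958 and 0.763), and its median was below 0 in both strains where the test pointed up. GLK1, GPM2, PYK2, PDC5, PDC6 and ADH5 stayed under the filter.

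In IMX605 against IMX372, the comparison of the locus labelled chromosome V with the native loci, 19 of 24 genes of the general stress response and 11 of 16 of the iron regulon rose. HSP12, which encodes a small membrane heat shock protein, rose from 58.1 ± 7.67 to 744 ± 201 FPKM, by 3.63 on the log2 scale (SE 0.17, adjusted p = 4.95e-08, limma). Other stress genes that rose were DDR2 (3.72), SIP18 (2.58), YGP1 (2.08) and HSP26 (1.87). Of 24 stress genes measured 19 rose and 0 fell, and 19 rose adjusted over the list alone, with a median change of 0.85 (camera, adjusted p = 9.13e-12, and adjusted p = 0.749 with an estimated correlation). The iron regulon, genes of iron uptake and sparing, had 11 of 16 risen and 0 fallen, or 14 adjusted over the list alone, with a median of 0.69 (camera, adjusted p = 8.16e-07, and adjusted p = 0.749 with an estimated correlation). FIT3, a cell wall mannoprotein that retains siderophore iron, rose from 30.6 to 443 FPKM, TIS11, an mRNA-binding regulator of the iron response, by 1.91, and FET3, a ferroxidase, by 0.63. Among trehalose and glycogen genes 9 of 18 rose and 1 fell, also adjusted over the list alone, with PGM2 up by 1.61, TSL1 up by 1.28 and GAC1, a phosphatase subunit, at -2.20 (camera, adjusted p = 0.00232, and adjusted p = 0.749 with an estimated correlation). Of 34 genes of the respiratory chain and ATP synthase 9 rose and 0 fell, also adjusted over the list alone, with COX9 up by 0.94 and ATP15 by 0.88 (camera, adjusted p = 0.00703, 0.0904 without IMX605 R7, and adjusted p = 0.749 with an estimated correlation).

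In lists of the translation machinery and of sterol synthesis, more genes fell than rose in IMX605. The ribosomal protein list names 137 genes, of which 21 had several gene models and 31 had none, so only 85 were tested. Of 85 cytosolic ribosomal protein genes 40 fell and 9 rose, or 47 and 12 adjusted over the list alone, with a median of -0.26 (camera, adjusted p = 0.000448, 0.0501 without IMX605 R7, and adjusted p = 0.749 with an estimated correlation). RPS0A fell from 1696 to 937 FPKM, by 0.86 on the log2 scale, whereas RPS28B rose from 3072 to 5588 FPKM. RPL4A and RPL4B, which are near-identical to each other and therefore uncertain, rose by 1.15 and 1.12. Of 58 ribosome biogenesis genes 19 fell and 0 rose, or 20 and 1 adjusted over the list alone, with YTM1 at -0.62, RRP1 at -0.60 and BRX1 at -0.61 (camera, adjusted p = 3.89e-05, and adjusted p = 0.749 with an estimated correlation). In ergosterol synthesis 11 of 23 genes fell and 1 rose, or 12 and 1 adjusted over the list alone. ERG11, lanosterol demethylase, changed from 719 ± 40.7 to 396 ± 5.58 FPKM (-0.86, adjusted p = 0.000114), ERG2 by -0.75 and ERG25 by -0.70, while MVD1 of the mevalonate branch rose by 0.51 (camera, adjusted p = 0.00232, and adjusted p = 0.749 with an estimated correlation). In sulfur assimilation 5 of 17 genes fell and 0 rose, or 8 and 1 adjusted over the list alone, with MET3 at -0.61 and MET17 at -0.60 (camera, adjusted p = 0.0158, 0.0920 without IMX605 R7 and 0.0681 without IMX372 DSE001, and adjusted p = 0.749 with an estimated correlation). The thiamine list had 8 of 18 genes risen and 1, the acid phosphatase gene PHO3, fallen, or 9 and 1 adjusted over the list alone (camera, adjusted p = 0.0109, and adjusted p = 0.749 with an estimated correlation). THI11, THI12 and SNZ3, which led it, have near-identical copies, and the list call ended without genes that have copies or an abundant opposite-strand neighbour (adjusted p = 0.649) and at a mean FPKM of at least 5 (0.140).

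In all, limma called 1635 of 5459 genes in IMX605 against IMX372, 818 higher and 817 lower, of which 207 and 111 changed by at least 2-fold. The balance moved with the scaling, to 960 higher and 762 lower with median-of-ratios factors and 764 and 1018 with equal sums. The lowest of the changes were those of JIP3 (-6.13), of MHF1 (-5.00), of IME4, an RNA methyltransferase gene of meiosis (-4.83, from 37.7 ± 2.43 to 0.363 ± 0.111 FPKM), of RRT12 (-4.30) and of TRX1 (-4.26). JIP3 meets the rule for near-identical copies, which a gene that overlaps another also meets, so its reads are uncertain. Opposite-strand RNA without a gene model lies outside the check for opposite-strand neighbours. Such reads were therefore not examined for IME4 and RRT12. URA3, a uracil synthesis gene widely used as a marker, rose from 263 ± 18.6 to 9506 ± 363 FPKM (5.17, adjusted p = 3.94e-11). It was also higher in IMX606. Effects of this difference in URA3 cannot be told apart from those of the locus in the comparisons against IMX372. Gene models PAD1 model 1 and MATALPHA2 model 3 had 0 reads in IMX372 and 21.6 and 16.0 FPKM in IMX605, at least 40.4-fold and 72.0-fold higher against a floor of 3 reads per library. Both overlap another gene model, so their reads are uncertain. The count was 1031 without IMX605 R12, 812 without IMX605 R7 and 802 without IMX372 DSE002.

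The other lists did not pass camera as a whole in IMX605 against IMX372, although each had members that limma called. Hexose transport and sensing (fry, adjusted p = 0.00845), chaperones (0.0133), the zinc regulon (0.0133), the DNA damage response (0.0243) and mating genes (0.0243) passed fry. The pentose phosphate pathway had 5 of 11 genes up and 3 down, with NQM1 at 2.44, SOL4 at 1.76, TKL2 at -1.14 and RKI1 at -0.61 (camera, adjusted p = 0.437). Of 17 chaperone genes 4 rose and 0 fell, with HSP60, the mitochondrial chaperonin, at 1.61 (adjusted p = 0.109). SSA1 and SSA2 also rose, but they have a near-identical copy or an abundant opposite-strand neighbour and are uncertain. The limma call of SSC1 ended with quantile normalization (adjusted p = 0.0527) and without the trend (0.0551). Zinc regulon genes had 4 of 7 down and 0 up, with the transporter genes ZRT1 at -0.99 and ZRT2 at -0.61 (adjusted p = 0.0536, 0.0391 without IMX605 R12, 0.0375 without IMX372 DSE001, 0.0424 at a mean FPKM of at least 5 and 0.0463 without genes with copies or opposite-strand neighbours). Glycerol and acetate metabolism had 7 up and 2 down of 16, with GPD1 at 0.70 (adjusted p = 0.164, 0.0442 without IMX372 DSE001 and 0.0304 at a mean FPKM of at least 5), and amino acid biosynthesis 9 up and 3 down of 34, with LYS1 at 0.77 (adjusted p = 0.179). Gluconeogenesis and glyoxylate genes had 4 up and 2 down of 10, with JEN1 at 1.01 and FBP1 at -1.67 (adjusted p = 0.333), TCA cycle genes 4 up and 0 down of 16 (0.340), phosphate genes 3 up and 0 down of 11 (0.488), and hypoxic genes 2 up and 3 down of 12, with TIR2 at -0.92 (0.903). Hexose transport and sensing had 4 up and 3 down of 11 (adjusted p = 0.958), with HXT15 and HXT6, both uncertain for their copies, at -3.00 and 1.79. Galactose genes had 1 of 6 down, GAL4 at -2.18 (0.543), the DNA damage response 3 up and 1 down of 11, with HUG1 at 1.12 (0.543), and mating genes 4 of 9 down, with PRM1 at -1.51 (0.144, and 0.0474 at a mean FPKM of at least 5). Median and mean differed in sign for the TCA cycle, phosphate and hexose transport lists, and the test took the sign of the mean in each. The relocated list passed without IMX372 DSE001 (adjusted p = 0.0339).

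**Figure D2:**
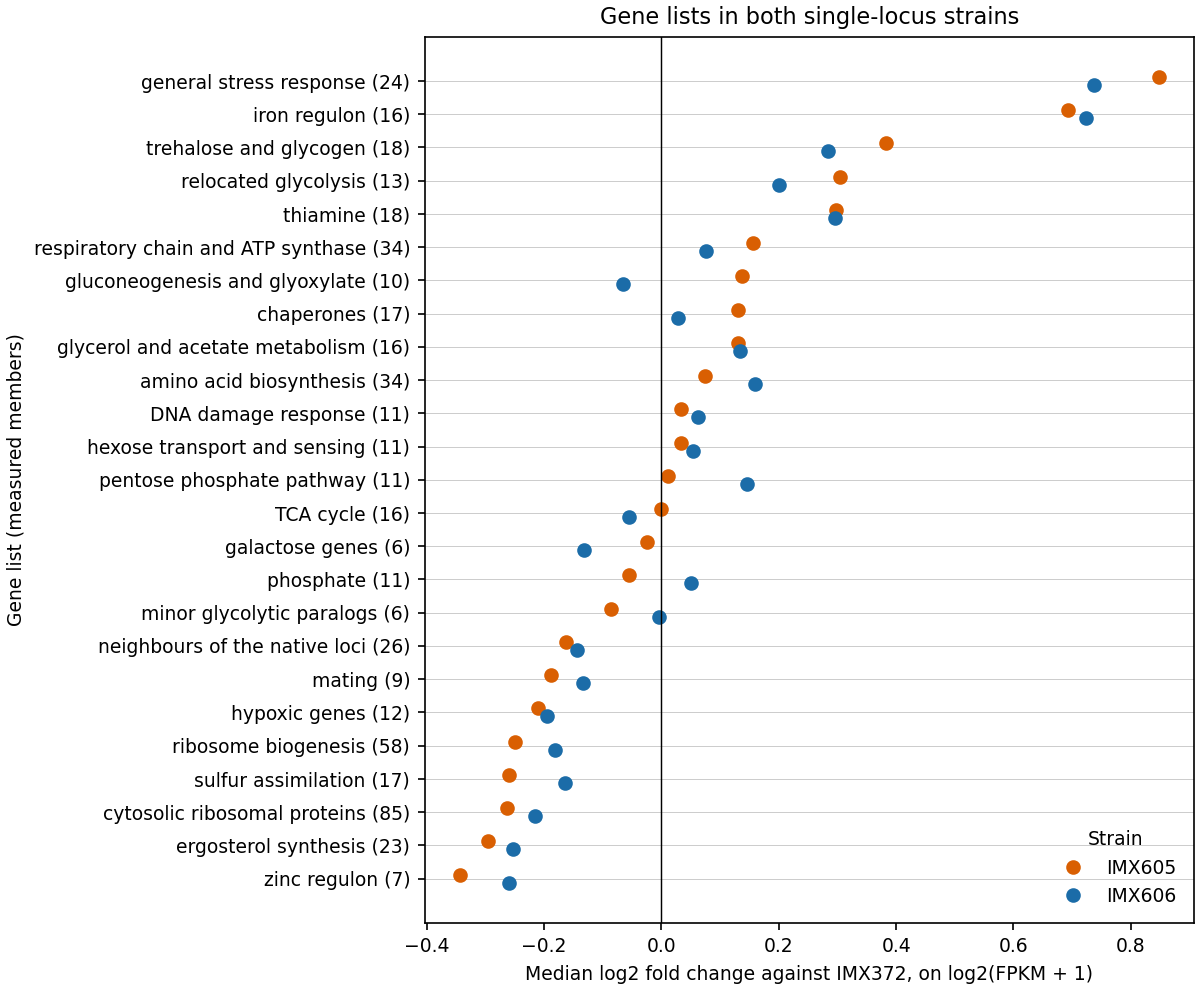
Median log2 fold change of each gene list (number of measured members in brackets) against IMX372 for IMX605 and IMX606, on log2(FPKM + 1). The general stress response (0.85 and 0.74) and the iron regulon (0.69 and 0.72) have the highest medians in both strains.

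In IMX606 against IMX372, the comparison of the locus labelled chromosome IX with the native loci, 15 of 24 stress genes and 12 of 16 iron genes rose. In the ribosomal and sterol lists more genes fell than rose. HSP12 stood at 509 ± 53.6 FPKM against 58.1 ± 7.67 (3.11, adjusted p = 1.76e-07, limma), and FIT3 at 427 ± 89.8 against 30.6 (3.74, adjusted p = 7.62e-07). Of the stress genes 15 of 24 rose and 0 fell, or 17 and 1 adjusted over the list alone (median 0.74; camera, adjusted p = 1.84e-10, and adjusted p = 0.714 with an estimated correlation). In the iron regulon 12 of 16 rose and 0 fell, or 13 adjusted over the list alone (median 0.72; adjusted p = 2.02e-09, and adjusted p = 0.714 with an estimated correlation). Amino acid biosynthesis had 10 of 34 up and 1 down, also adjusted over the list alone, with LYS1 at 0.85 (adjusted p = 0.00986, and adjusted p = 0.725 with an estimated correlation). Trehalose and glycogen genes had 7 of 18 up and 1 down, also adjusted over the list alone (adjusted p = 0.0125, and adjusted p = 0.725 with an estimated correlation). Ribosomal protein genes had 35 of 85 down and 9 up, or 37 and 11 adjusted over the list alone, with RPS0A at -0.78 (adjusted p = 0.00997, and adjusted p = 0.781 with an estimated correlation). Ribosome biogenesis genes had 13 of 58 down and 0 up, also adjusted over the list alone (adjusted p = 0.00486, and adjusted p = 0.745 with an estimated correlation). Ergosterol genes had 11 of 23 down and 1 up, also adjusted over the list alone, with ERG11 at -0.78 and ERG2 at -0.72 (adjusted p = 0.00746, and adjusted p = 0.725 with an estimated correlation).

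The thiamine list in IMX606 had 9 of 18 up and 1 down, or 9 and 2 adjusted over the list alone (camera, adjusted p = 0.0125, and adjusted p = 0.725 with an estimated correlation). This call ended without genes that have copies or an abundant opposite-strand neighbour (0.657) and at a mean FPKM of at least 5 (0.146). Respiratory chain and ATP synthase genes, with 7 of 34 up and 2 down, did not pass in IMX606 (adjusted p = 0.112, 0.0489 without IMX606 R13), nor did sulfur assimilation, with 4 of 17 down (0.178). Up and down counts in the remaining lists were 5 and 3 of 11 for the pentose phosphate pathway (adjusted p = 0.178), 4 and 0 of 17 for chaperones (0.119), 0 and 3 of 7 for the zinc regulon (0.0821, 0.0439 without IMX372 DSE001) and 6 and 2 of 16 for glycerol and acetate metabolism (0.119, 0.0259 without IMX372 DSE001 and 0.0181 at a mean FPKM of at least 5). They were 4 and 1 of 10 for gluconeogenesis (0.368), 2 and 0 of 16 for the TCA cycle (0.630), 2 and 0 of 11 for phosphate (0.432), 2 and 3 of 12 for hypoxic genes (0.921) and 3 and 3 of 11 for hexose transport (0.932). For galactose genes they were 0 and 2 of 6 (0.322), for the DNA damage response 2 and 1 of 11 (0.459), and for mating genes 0 and 2 of 9 (0.119). Hexose transport (fry, adjusted p = 0.000540), chaperones (0.0182), the zinc regulon (0.0182), galactose genes (0.0463) and mating genes (0.0304) passed fry in IMX606. Leaving out IMX606 R8 lowered the number of list calls from 9 to 4, ending those of ribosomal proteins (0.321), ribosome biogenesis (0.133), trehalose and glycogen (0.0745), amino acid biosynthesis (0.0745) and thiamine (0.0674). Without IMX372 DSE002 the amino acid (0.0565) and thiamine (0.0501) calls ended, and without IMX372 DSE001 the relocated list passed (0.0269). Median and mean differed in sign for the gluconeogenesis, TCA cycle, hexose transport and minor paralog lists.

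Limma called 1304 of 5459 genes in IMX606 against IMX372, 604 higher and 700 lower, of which 179 and 104 changed by at least 2-fold. With median-of-ratios scaling 740 of 1298 calls were higher, 57.0% against 46.3%, and with equal sums 581 of 1363. The count was 597 without IMX372 DSE002. The lowest changes were again those of JIP3 (-6.10), IME4 (-4.91), TRX1 (-4.59), MHF1 (-4.33) and RRT12 (-4.24), and URA3 rose by 5.29 to 10336 ± 800.4 FPKM (adjusted p = 3.04e-11).

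Both single-locus strains were set against the same 2 control libraries, so their calls were compared with that in mind. Of the called genes 1162 changed alike in IMX605 and IMX606, 559 higher and 603 lower, and 1 changed in opposite directions, the subtelomeric gene model PAU1 model 2. With median-of-ratios scaling 670 were higher and 505 lower in both, and with equal sums 533 and 700. Independent lists of these sizes would share 90.5 higher and 105 lower genes, and unchanged groups simulated against the same controls shared 0.04 on average and at most 1 in 100 simulations. The simulations drew noise independently for each gene and library. They leave out deviations that many genes of a library share, so their values may lie below what such deviations would give. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.943 (0.5004 in the simulations) with a covariance of 0.2998 (0.00966 in the simulations), a difference of 0.290. Signs were the same for 88.8% of genes against 66.6% simulated. With 1 control library for each comparison, a split chosen after seeing the data, 552 genes changed alike with DSE001 for IMX605 and DSE002 for IMX606 and 505 the other way round. The covariance was 0.292 and 0.289, and independent lists would share 32.9 higher and 32.6 lower genes in the first split and 31.9 and 33.2 in the second. Lone control libraries take their spread from the other strains and come from the same library set, so part of the excess may still come from the controls. Without IMX605 R7 the alike count was 749, and without IMX372 DSE002 it was 549.

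Genes beside the native loci of the relocated genes changed in both strains. TRX1, a thioredoxin gene next to PDC1, read 1580 ± 126 FPKM in IMX372 and 81.2 ± 1.59 and 65.8 ± 18.8 in IMX605 and IMX606. PDX1, next to TDH3 and coding for a subunit of pyruvate dehydrogenase, fell by 2.44 and 2.16 on the log2 scale, MSI1 next to PGI1 by 1.12 and 1.26, and ADP1 next to PGK1 by 1.00 and 0.89. The vacuolar copper transporter gene CTR2 next to ENO2 rose from 148 ± 7.15 to 848 ± 49.0 and 860 ± 4.97 FPKM, and both neighbours of PFK2 rose, YMR206W by 2.39 and 2.29 and INP1 by 1.36 and 1.44. MHF1 next to ADH1 (-5.00 and -4.33), YHR173C next to ENO2 (-2.99 and -2.95) and BLI1 next to FBA1 (-1.24 and -1.56) changed too, but lie close to a far more abundant gene on the opposite strand and are uncertain. Of the 26 neighbours measured, those of CAN1 and SGA1 included, 6 rose and 11 fell in IMX605, or 7 and 11 adjusted over the list alone. In IMX606 5 rose and 10 fell, or 5 and 11 adjusted over the list alone. As a list the neighbours did not pass camera, which tests for a shift in a single direction (adjusted p = 0.0744 and 0.137). In IMX605 the camera result changed side with single libraries left out and with only the 2 groups in the fit (0.0309). By fry the list passed in both strains (adjusted p = 0.0243 and 0.0315).

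**Figure D3:**
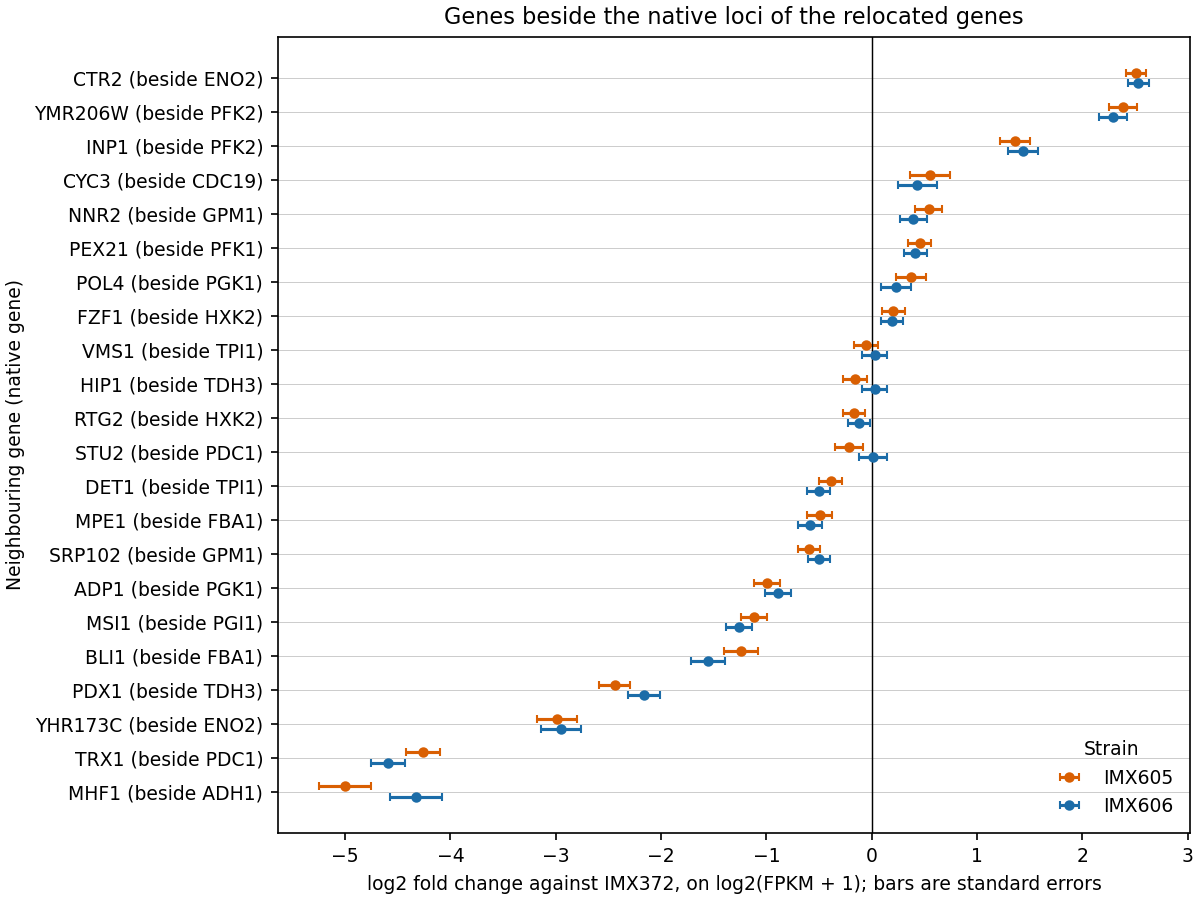
Log2 fold change against IMX372 of the genes beside the native loci of the relocated genes, with standard errors, for IMX605 and IMX606. TRX1 beside PDC1 lies at -4.26 and -4.59, and CTR2 beside ENO2 at 2.51 and 2.53.

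IMX605 against IMX606, the comparison of both labelled positions of the single locus, gave few differences. CAN1, the arginine permease gene (chromosome V, 32674 to 34446), read 9.47 ± 0.436 FPKM in IMX605, 119 ± 0.343 in IMX606 and 100.4 ± 10.2 in IMX372 (SD, n = 2 each), a log2 difference of -3.52 between the single-locus strains (SE 0.11, adjusted p = 7.36e-09, limma). On chromosome IX, FMC1 (174028 to 174495), a mitochondrial assembly factor gene, read 4.67 ± 2.85, 78.5 ± 14.6 and 87.5 ± 5.58 FPKM, and the adjacent FYV10 (174683 to 176233) read 5.31 ± 0.396, 17.7 ± 0.597 and 15.4 ± 3.29. SGA1, a sporulation glucoamylase gene on the other side of FMC1 (172264 to 173913), had 1 read in IMX605, 96 in IMX606 and 268 in IMX372, and is uncertain because FMC1 on the opposite strand is far more abundant. Per read on genes that is 1.06% of the IMX606 level, with a 95% exact interval from 0.0264% to 6.02% that covers counting error alone, not the spread between cultures. Its difference of -1.26 on the log2(FPKM + 1) scale did not pass (adjusted p = 0.178), but passed with a pseudocount of 0.1 (0.0166), without limma's trend (0.00831), without IMX606 R13 (0.0110) and in voom on the recovered reads (0.000303). Against IMX372 SGA1 fell by 1.34 in IMX605 (adjusted p = 0.00266, 0.0610 without IMX372 DSE001). The libraries labelled IMX605 were thus low in genes on both chromosomes named in the labels, and those labelled IMX606 in 0 genes on either at under 25% of both other strains.

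**Figure D4:**
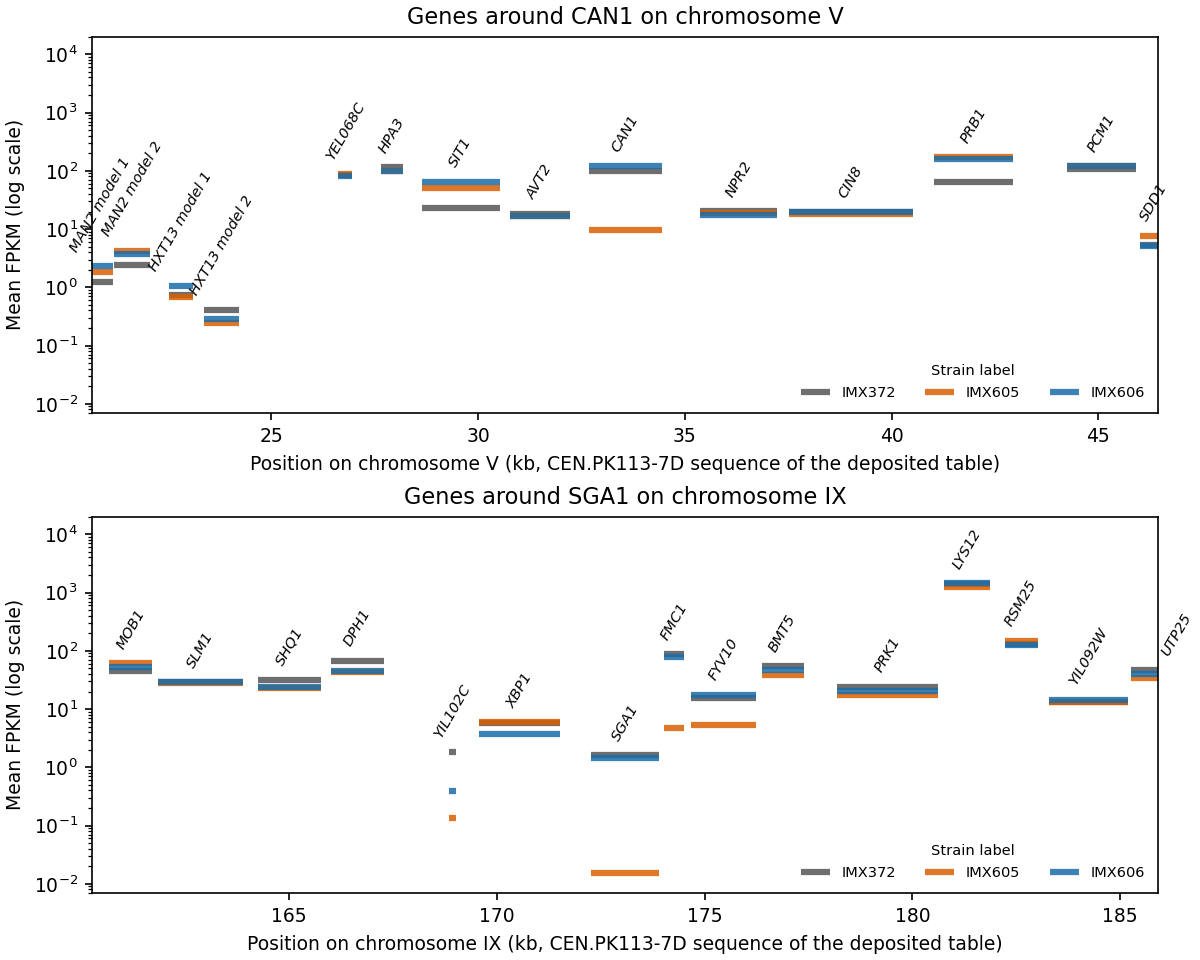
Mean FPKM (log axis) of the genes within 12 kb of CAN1 on chromosome V and of SGA1 on chromosome IX, each drawn over its span, for the 3 strain labels. CAN1 (9.47 FPKM against 119 and 100.4) and FMC1 (4.67 against 78.5 and 87.5) are low in the libraries labelled IMX605, and SGA1 has 1 read there.

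In total 11 of 5459 genes were called between the single-locus strains, 4 higher and 7 lower in IMX605, and 199 had an unadjusted p under 0.05. Higher in IMX605 were PAU20 model 2, a subtelomeric seripauperin gene model (52.8 against 0.262 FPKM), AAD15, YOL163W and YOL162W, which all lie at the left end of chromosome XV. Lower were PAU1 model 2, CAN1, FMC1, FYV10 and the 2-micron plasmid genes R0020C, R0030W and R0040C, which lay 0.66 to 0.69 lower on the log2 scale. PAU20 model 2, PAU1 model 2 and AAD15 have near-identical copies and are uncertain. The calls of the plasmid genes ended without IMX605 R12 (adjusted p = 0.109 to 0.128), IMX605 R7 (0.0522 to 0.0702), IMX372 DSE001 (0.0696 to 0.123) or IMX372 DSE002 (0.0713 to 0.126), that of YOL162W without IMX372 DSE001 (0.0505) or DSE002 (0.0511), and that of AAD15 without IMX605 R7 (0.134), IMX372 DSE001 (0.101) or DSE002 (0.104). Without the filter on low values the calls of AAD15 (0.249), YOL162W (0.134), FYV10 (0.0652), R0020C (0.0652), R0030W (0.110) and R0040C (0.154) ended too, as did those of the 3 plasmid genes without limma's trend (0.0639 to 0.0746), and voom did not call AAD15 (0.238). With only the 2 groups in the fit AAD15 (0.0988), YOL162W (0.0555), R0020C (0.0767), R0030W (0.0767) and R0040C (0.136) were not called. The count was 7 without IMX605 R7, 97 without IMX606 R13, 17 without IMX606 R8 and 6 without either IMX372 library, 5 without the filter on low values and 6 with only the 2 groups in the fit.

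Between the single-locus strains the gene lists moved little. Camera passed 9 of 26 lists, namely the CAN1, SGA1 and URA3 list used to check labels (adjusted p = 5.75e-13, and adjusted p = 0.117 with an estimated correlation), ribosomal proteins (5.12e-05), ribosome biogenesis (0.000107), amino acid biosynthesis (0.000107), sulfur assimilation (0.000201), the iron regulon (0.0314), general stress (9.28e-06), respiratory chain (0.000362) and trehalose and glycogen (0.00554). Medians of the last 8 lay between -0.10 and 0.17, with 0 members called by limma or voom, and between 0 and 4 members of each had an unadjusted p under 0.05. With an estimated correlation none of them passed (adjusted p = 0.769 with an estimated correlation for each). The iron regulon call also ended without the filter on low values (camera, adjusted p = 0.0726). Without IMX605 R7 3 lists passed, the calls of ribosomal proteins (0.384), ribosome biogenesis (0.996), trehalose and glycogen (0.994), respiratory chain (0.866), general stress (0.551) and sulfur assimilation (0.196) having ended. Without IMX606 R13 4 passed, ribosomal proteins (0.974), ribosome biogenesis (0.974), trehalose and glycogen (0.261), respiratory chain (0.422) and general stress (0.0901) having ended. Amino acid biosynthesis ended without IMX606 R8 (0.0926) and the iron regulon without IMX606 R8 (0.313) or IMX605 R12 (0.514). The label check list passed in IMX606 against IMX372 (adjusted p = 0.0194, and adjusted p = 0.714 with an estimated correlation), a call that ended without the filter (0.0586), and did not pass in IMX605 against IMX372 (adjusted p = 0.595), where its median and test were below 0 and its mean above. The other 17 lists did not pass between the single-locus strains; without IMX606 R8 the TCA cycle (0.000948), minor paralog (0.00324), phosphate (0.00324) and thiamine (0.00425) lists did, as did the TCA cycle without IMX605 R12 (0.00169).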

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

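The tests of near-identical copies, swapped labels, depth and neighbours below were chosen only after the result was seen, and those of strand and library set before. Between the single-locus strains 11 genes differed by limma, and each is listed because the change against the shared IMX372 libraries differs between IMX605 and IMX606. On the log2 scale (IMX605 minus IMX606) these are PAU20 model 2 (5.41), AAD15 (1.24), YOL163W (1.06), YOL162W (1.01), PAU1 model 2 (-5.38), FMC1 (-3.90), CAN1 (-3.52), FYV10 (-1.57), R0040C (-0.69), R0030W (-0.69) and R0020C (-0.66). PAU1 model 2 had 0 reads in IMX605, at least 96.1-fold lower than IMX606 and 27.0-fold lower than IMX372 against a floor of 3 reads per library. PAU20 model 2, PAU1 model 2 and AAD15 have near-identical copies. Groups of 2 cultures allow no test for outlying libraries.

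The first pattern is that 559 genes rose and 603 fell in both single-locus strains. Genes with a near-identical copy made up 14.85% of those that rose against 2.986% of all tested genes. Their median change exceeded that of other genes by 0.6124 (0.56 against -0.05, interquartile range 1.26, 163 genes), so shared reads may account for part of the rises. The rule for copies also takes in overlapping genes and leaves out shorter or less similar stretches, so 14.85% of the 559 is no upper bound. Among 182 genes at the floor in both strains, a far higher opposite-strand gene lay beside 31.25% of the 32 that were higher in IMX372 and 19.33% of the other 150, a difference of 11.92 percentage points (Fisher exact p = 0.156, 95% interval -3.14 to 30.1). With the gene's own level taken from the single-locus strains the difference was 17.5 (exact p = 0.0396) and from IMX372 1.21 (exact p = 0.816), so reads counted without regard to strand stay open. Library batch cannot be told apart from strain, since 0 strains have libraries in both sets, and the difference in strain, which the design names, stays open too.

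The second pattern is the loss of CAN1 on chromosome V and of SGA1, FMC1 and FYV10 reads on chromosome IX in the libraries labelled IMX605. The tables argue against lower depth, since the reads on genes, summed over both libraries, differed between IMX605 and IMX606 by a log2 ratio of -0.01844. For swapped labels, the libraries labelled IMX606 had 0 genes on either chromosome under 25% of both other strains, and those labelled IMX605 had 1 on V and 2 on IX (SGA1 and FMC1). The labels give only the chromosome and name neither the locus nor a lost gene, and losses on both chromosomes in one strain decide for neither assignment, so a swap stays open. The loss of SGA1 is not shown to be separate from that of FMC1, far more abundant on the opposite strand, and a strain difference in these regions was not tested.

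The third pattern is the change of genes beside the native loci of the relocated genes. Their median absolute change over both strains was 0.546 for 22 genes, against 0.315 for 23 neighbours of minor paralogs and a 95th percentile of 0.3174 over 10000 random sets. This argues only against a batch acting on all genes alike, which would give no such excess over random genes. The random sets were matched for size and not for lying beside abundant genes. The 22 genes also include MHF1, YHR173C and BLI1, whose reads are uncertain. The direct comparison of both neighbour sets missed the threshold (permutation p = 0.0586, 100000 resamples), so a difference between them is not shown. A batch that acts on single regions or kinds of genes was not tested and stays open, as does, as a hypothesis, an effect of removing the native genes on their neighbours.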

How the results depend on the processing

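The tests with voom, without genes that have copies or opposite-strand neighbours, and with the controls split were chosen only after the result was seen. No paired analysis was possible because the columns of the table carry no replicate number; a block guessed from the order of the library numbers was not tried. Tests on deposited counts were not run, since the table holds FPKM, and where a library is left out the lone culture is assumed to vary like the other strains. Genes called with each library left out in turn ranged from 802 (without IMX372 DSE002) to 1942 (without IMX606 R8) for IMX605 against IMX372, from 597 (without IMX372 DSE002) to 1256 (without IMX606 R8) for IMX606 against IMX372, from 6 (without either IMX372 library) to 97 (without IMX606 R13) between the single-locus strains, and from 549 to 1146 for genes changed alike, which numbered 552 and 505 with 1 control library for each comparison (fewer libraries per test). Without the filter 5 genes and with only the 2 groups compared 6 genes were called between the single-locus strains. Lists passing ranged from 7 to 11 for IMX605 against IMX372, from 4 (without IMX606 R8) to 12 (without IMX372 DSE001) for IMX606 against IMX372, and from 3 (without IMX605 R7) to 11 (without IMX606 R8) between the single-locus strains. Camera with an estimated correlation passed 0, 0 and 0 lists in the 3 comparisons (26 lists each, with 9, 9 and 9 at the preset correlation and 12, 9 and 1 with fry). Fry passed partly other lists. In IMX605 against IMX372 ribosomal proteins (fry, adjusted p = 0.0930), ribosome biogenesis (0.0897), trehalose and glycogen (0.0732) and the respiratory chain (0.190) missed it. In IMX606 against IMX372 ribosomal proteins (0.173), ribosome biogenesis (0.168), trehalose and glycogen (0.173) and amino acid biosynthesis (0.0646) missed it. Thiamine and ergosterol synthesis (0.0510 each) missed it there too. With equal sums the summed transcript of the relocated genes was 80374 in IMX605 and 78502 in IMX606, against 72772 in IMX372. Between the single-locus strains the direction turned with a library left out for ribosomal proteins (adjusted p 1.10e-12 to 0.974 over the libraries), ribosome biogenesis (2.61e-10 to 0.996) and the iron regulon (3.23e-05 to 0.514); the cause was not tested. Of named gene results under the other planned settings 2708 of 2792 kept their side of the threshold, 76 lost and 8 gained a call, with 1736 of 1890 kept, 146 lost and 8 gained with a library left out and 553 of 558 kept with the added tests. Of list results 687 of 696 kept theirs under other planned settings and 426 of 468 with a library left out. Named gene calls that held with every library left out were 114 of 140, 95 of 126 and 6 of 11 in the 3 comparisons. Voom called 1779, 1417 and 11 genes, and 1438, 1097 and 8 were called without copies and opposite-strand neighbours. Genes under about 0.160 FPKM at 1 kb rest on fewer than 3 reads in the shallowest library.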

Other observations

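Several genes that are not direct neighbours of the native loci were also much lower in both single-locus strains than in IMX372. The sporulation gene RRT12 (28.8 against 0.511 FPKM in IMX605 and 0.588 in IMX606) and the meiotic splicing factor gene MER1 (log2 change -3.34 in both) fell in both strains, as did YKL070W (-4.16 and -3.80) and YPR027C (-3.98 and -3.95). Reads from opposite-strand RNA without a gene model were not examined for these genes, and the strand setting of the counting is not given. The 2-micron plasmid gene R0010W stood at 27.7 and 42.7 FPKM against 418. The other plasmid genes, R0020C, R0030W and R0040C, rose in IMX606 against IMX372 by 0.61, 0.83 and 0.93 (adjusted p = 0.000852, 0.000137 and 7.19e-05) and were not called in IMX605 against IMX372 (-0.05, 0.14 and 0.23; adjusted p = 0.729, 0.326 and 0.114). SPG4 (3.28 and 3.20) was among the 10 largest rises in both strains and RTC3 (3.18) in IMX605.

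Same-strain libraries correlated at 0.996 for IMX605, 0.992 for IMX606 and 0.996 for IMX372. The squared difference per gene relative to counting error was 18.6, 42.1 and 42.5 in these pairs, and 7.97 for IMX605 R12 against IMX606 R13, libraries of different strains. The first principal component held 79.4% of the variance and separated IMX372 from the other strains, and the second held 8.04%, with IMX606 R8 at -12.22.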
